A study of Mus musculus with 9 samples.

How the data were processed

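Total RNA of mouse pancreatic islets was measured by RNA sequencing in 9 libraries, 3 in each of 3 groups. Control islets were untreated, inflamed islets were exposed for 48 hours to interleukin-1 beta, tumor necrosis factor alpha and interleukin-6, and particle islets received the same cytokines together with the nanoparticles under study. Groups and replicate numbers were taken from the sample titles, per the labels. The untreated columns carried a name without the group word and were matched as the one set of 3 left once the inflamed and particle columns had been matched by name.

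The deposited table of counts holds whole-number read counts per gene, not normalized, for 56748 genes. Per the submitters' processing notes, HTSeq, DESeq2 and the mouse genome build GRCm39 were used, with versions not given in the sources used here. The deposited table of FPKM values (fragments per kilobase of gene, scaled by library) has the same genes and libraries. In that table each FPKM value equals the deposited count divided by gene length and by 1 constant per library. That constant differed from the library's total count by a factor of 0.861 to 1.19. Whether counting used the strand of the reads, and how the replicates of a group were obtained (separate animals, islet batches or repeated libraries), is not given in the sources used here. P-values therefore measure the spread between these samples, which may be partly technical. Gene names and coordinates (GRCm39, counted from 1) are those of the deposited tables. The reference genome provided was an earlier mouse build and was not used.

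Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with the default of filterByExpr (a smallest count of 10), which left 17276 genes. Libraries were scaled by TMM factors, and quasi-likelihood models with robust dispersion estimates were fitted to all 9 libraries. The 3 comparisons were inflamed against control, particle against inflamed, and particle against control. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. Expression is given as CPM computed with the TMM-scaled totals. A fold against a group with no count is a lower bound computed from 3 counts over the group. These floors and all counting intervals (95%) cover counting error only. Chi-square statistics per degree of freedom between replicates of a group were 43.4 to 207, so no pair of libraries differed by as little as sampling noise, and all 9 were kept.

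The comparisons, tests and alternatives, the rule for naming genes and 31 lists of genes were fixed before the data were examined. The named genes were the 8 largest changes in each direction among called protein-coding genes with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a clone name; up to 3 members of each list with the smallest adjusted p; and 13 genes of islet function and inflammation in every case. Genes chosen in another way are named as such. Lists were tested with camera at a preset correlation between genes of 0.01, and the 93 list tests (31 lists in 3 comparisons) were adjusted together. An estimated correlation and fry (limma 3.58.1) were run beside it. Of 691 symbols listed, 7 were not found under the same symbol and 39 more did not pass the count filter. Adjusted over the list alone means that p-values were adjusted over the tested members of 1 list. The 9 lists of cell type markers cover alpha, delta (with PP and epsilon), acinar, duct, stellate, endothelial, macrophage, lymphocyte (with neutrophil) and neural cells.

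Alternatives were DESeq2-style (RLE) factors, library totals without TMM factors, scaling without the 20 most abundant and the mitochondrially encoded genes, no count filter, a stricter filter (at least 1 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, non-robust dispersions, fits of only the compared libraries, a replicate block, glmTreat against a fold of 1.5, limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1), and leaving out each library in turn. Thinning of all libraries to 17832949 counts was chosen after seeing the data.

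The procedure was tested on simulated counts with the means and totals of the real libraries. Of 100 genes planted at 4-fold, 47% were recovered for inflamed against control (16759 genes in that step), 57% for particle against inflamed (16688 genes) and 48% for particle against control (16767 genes). Of 100 genes planted at 2-fold, the shares were 8%, 11% and 8%. No planted gene was called in the wrong direction, and 1, 4 and 0 unchanged genes were called. A list planted at 2-fold was found in all 3 simulated comparisons (16653, 16680 and 16733 genes in that step), with 0 other lists called. Genes were drawn independently in these simulations, so they do not show how often lists are called when genes vary together. Other splits of the real libraries called 10 to 21, 8 to 23 and 13 to 20 lists in the 3 comparisons at the preset correlation. Each of those splits mixes the compared groups in unequal numbers and so keeps part of any group difference. Their counts are therefore not a rate of false calls.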

Results

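To characterise the response of pancreatic islets to inflammatory cytokines with and without nanoparticles, total RNA of primary islets from wild-type C57BL/6 mice was sequenced in 3 groups of 3 libraries. Control islets were untreated. Inflamed islets were cultured for 48 hours with interleukin-1 beta, tumor necrosis factor alpha and interleukin-6, a mixture that models the inflammatory environment of islets. Particle islets received the cytokines together with polydopamine-coated mesoporous silica nanoparticles made for controlled delivery of nutrients. The stated aim was to examine protection by the particles under cytokines, with attention to functional and immune pathways. No library with particles alone was analysed here, so the effect of the particles is measured only in the presence of cytokines. The total count per library ranged from 17832949 to 55865759.

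Insulin transcripts took 28.8 ± 0.351% of all counts (SD, n = 3) in control islets, 17.7 ± 4.23% in inflamed islets and 15.4 ± 6.56% in particle islets. The exact two-sided permutation p of both treated groups against control was 0.1, the smallest that 3 against 3 libraries allow. Mitochondrially encoded transcripts took 1.79 ± 0.141%, 0.992 ± 0.211% and 1.28 ± 0.226% of counts in the same order. The first principal component held 60.8% of the variance and separated control from inflamed islets, with the particle libraries at 37.9, -22.7 and 80.5. Particle replicate 3, at 80.5, lay beside inflamed replicate 1 at 82.1, and the other particle libraries lay between the groups. Particle replicate 2 lay closest to the controls and held 21.6% insulin and 0.742% glucagon transcripts, against 8.55% and 16.1% insulin in particle replicates 1 and 3. Across genes, the correlation between libraries of a group was 0.962 to 0.98 in controls, 0.908 to 0.952 in inflamed and 0.922 to 0.945 in particle islets. Between groups it was 0.894 to 0.965 for particle and inflamed, 0.82 to 0.931 for particle and control, and 0.784 to 0.839 for inflamed and control libraries. The closest pair of a particle and an inflamed library was thus more alike than any pair within either of these groups.

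**Figure D1:**
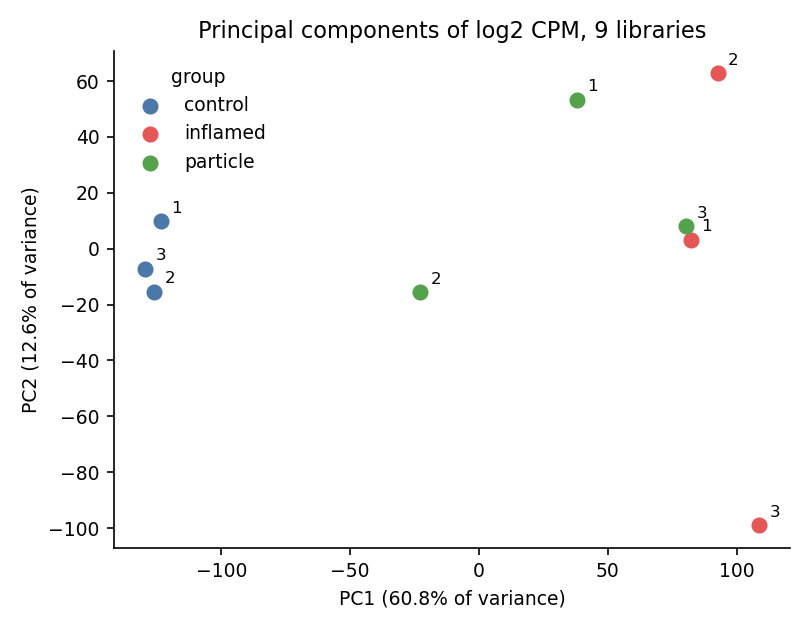
Each point is 1 library placed by its first (60.8% of variance, x axis) and second (12.6%, y axis) principal components of log2 CPM, colored by group and numbered by replicate. The 3 control libraries lie together at the left, the inflamed libraries at the right, and particle replicate 2 lies between them at -22.7 on the first component.

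To define the cytokine response, inflamed islets were compared with control islets. The inflammatory genes Nos2 and Cxcl9 were overexpressed, and the beta cell genes Mafa and Slc2a2 were underexpressed. Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11 from 78811613 to 78851080), was expressed at 618 ± 118 CPM (SD, n = 3) against 0.573 ± 0.656 CPM in controls, a log2 fold change of 10.10 (SE 0.81, adjusted p = 8.96e-05). Cxcl9, a chemokine that recruits lymphocytes (ENSMUSG00000029417, chromosome 5 from 92469206 to 92475938), reached 945 ± 266 CPM against 0.101 ± 0.0886 CPM (log2 fold change 13.20, SE 0.79, adjusted p = 1.23e-06). The log2 fold change of Nos2 was 9.46 without control replicate 1 and 11.35 without control replicate 2, and that of Cxcl9 was 12.52 without control replicate 3. Mafa, a transcription factor that drives insulin expression in mature beta cells (ENSMUSG00000047591, chromosome 15 from 75617339 to 75620077), fell from 2781 ± 228 to 54.4 ± 14.6 CPM (log2 fold change -5.68, SE 0.996, adjusted p = 0.0064). Slc2a2, which encodes the glucose transporter GLUT2 of beta cells (ENSMUSG00000027690, chromosome 3 from 28752052 to 28785508), fell from 402.5 ± 88.2 to 8.67 ± 2.47 CPM (log2 fold change -5.54, SE 0.80, adjusted p = 0.00235).

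Among 30 NF-kB targets and chemokines, 29 rose, 0 fell and 1 was not called (adjusted p of the list 2.04e-32, and adjusted p = 0.0958 with an estimated correlation). Cxcl10, a lymphocyte-recruiting chemokine, rose from 1.14 ± 1.01 to 993 ± 236 CPM, Ccl2, which recruits monocytes, from 0.423 ± 0.431 to 164 ± 88.3 CPM, and Cd40, a costimulatory receptor, from 1.203 ± 0.0501 to 269.8 ± 40.9 CPM. Il6, which encodes interleukin-6, rose from 0.361 ± 0.565 to 49.6 ± 21.5 CPM. In the list of IL-6, STAT3 and acute phase genes, 21 of 27 rose and 1 fell (adjusted p of the list 3.30e-08, and adjusted p = 0.292 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, rose from 29.0 ± 12.9 to 68.1 ± 10.6 CPM. All 31 interferon response genes rose (adjusted p of the list 1.24e-72, and adjusted p = 0.0356 with an estimated correlation), among them Rsad2, an antiviral enzyme, from 1.84 ± 0.201 to 148 ± 17.2 CPM and Xaf1, a pro-apoptotic interferon target, from 1.80 ± 0.673 to 219 ± 28.0 CPM. All 18 genes of MHC class I antigen presentation rose (4.63e-45, and adjusted p = 0.0485 with an estimated correlation). B2m, the light chain of class I molecules, went from 39.3 ± 4.02 to 5344 ± 849 CPM. Of 14 complement genes, 8 rose and 1 fell, with 9 higher and 2 lower adjusted over the list alone (7.23e-06, and adjusted p = 0.196 with an estimated correlation). C1ra, a protease of the first complement component, rose from 1.16 ± 0.249 to 629 ± 105 CPM. C1ra and the H2-Q class I genes have close paralogs, and Gbp4, Irf7 and Ifnl2 overlap other expressed genes, so the share of each such gene in its counts is uncertain. The 29, 21, 31 and 18 members higher in the NF-kB, IL-6, interferon and class I lists were the same in number when adjusted over the list alone.

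Genes of cell stress and death also rose, in the same libraries in which 19 of 21 macrophage markers rose. In the list of nitric oxide, oxidative stress and NRF2 genes, 20 of 27 rose and 1 fell, also adjusted over the list alone (5.86e-08, and adjusted p = 0.196 with an estimated correlation). Sod2, the mitochondrial superoxide dismutase, rose from 105 ± 13.4 to 488.5 ± 150.2 CPM and Nqo1, an NRF2-controlled quinone reductase, from 8.57 ± 0.562 to 49.2 ± 7.58 CPM. Of 27 genes of apoptosis and cell death, 20 rose and 0 fell, also adjusted over the list alone (2.16e-14, and adjusted p = 0.0958 with an estimated correlation). The list mixes genes that promote and genes that restrain cell death. Bcl2l1, Mcl1 and Cflar, which restrain it, were among the 20, so the count gives no direction of cell death. Fas, a death receptor, rose from 0.222 ± 0.143 to 46.7 ± 5.14 CPM, Casp4, an inflammatory caspase, from 0.210 ± 0.145 to 62.9 ± 11.6 CPM, and Mlkl, the effector of necroptosis, from 1.996 ± 0.226 to 91.4 ± 9.17 CPM. Among 20 immediate early genes 11 rose and 0 fell, also adjusted over the list alone (0.00162, and adjusted p = 0.419 with an estimated correlation), with Jun at 276 ± 101 against 38.7 ± 10.96 CPM. Genes of endoplasmic reticulum stress and the unfolded protein response went the other way as a list (0.0117, and adjusted p = 0.499 with an estimated correlation). There 2 of 22 rose and 11 fell, or 2 and 14 adjusted over the list alone. Atp2a2, the calcium pump SERCA2, fell from 1249 ± 66.2 to 307 ± 102 CPM and Hyou1, a chaperone, from 1023 ± 221 to 335 ± 59.4 CPM. In the integrated stress response list 7 of 25 rose and 5 fell, or 7 and 6 adjusted over the list alone, and the list was not called (adjusted p = 0.387). Atf3, a stress-induced transcription factor in that list, rose from 5.77 ± 0.453 to 156 ± 14.4 CPM.

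Beta cell transcripts fell broadly, together with the share of counts from insulin. Of 27 beta cell identity genes 25 fell and 0 rose, also adjusted over the list alone (3.14e-17, and adjusted p = 0.348 with an estimated correlation). Pdx1, a transcription factor of pancreas and beta cells that overlaps the antisense gene Plut and is therefore uncertain, was at 13.6 ± 1.99 against 212 ± 11.9 CPM, and Slc30a8, the zinc transporter of insulin granules, fell from 441 ± 47.4 to 45.6 ± 3.75 CPM. G6pc2, the glucose-6-phosphatase subunit of islets and a member of the same list, fell from 996 ± 311 to 11.1 ± 3.88 CPM. Of 28 genes of stimulus-secretion coupling and exocytosis, 17 fell and 0 rose, or 17 and 1 adjusted over the list alone (2.97e-07, and adjusted p = 0.383 with an estimated correlation). Sytl4, which docks insulin granules, fell from 187 ± 64.5 to 22.5 ± 2.38 CPM. Of 17 genes of hormone processing and granules 8 fell, or 9 adjusted over the list alone, and 0 rose (0.00584, and adjusted p = 0.44 with an estimated correlation). Pcsk1, the prohormone convertase, fell from 279.8 ± 88.7 to 55.9 ± 10.3 CPM and Scg2, a granin, from 3708 ± 134 to 611 ± 103 CPM. Ins1 (chromosome 19 from 52252735 to 52253914) fell from 81270 ± 2913 to 23360 ± 10800 CPM (adjusted p = 0.0491). That call was lost without any 1 of the 3 control or 3 inflamed libraries or particle replicate 3 (adjusted p of Ins1 up to 0.135), and with limma on FPKM (0.312). Ins2 was not called at 153000 ± 44510 against 238700 ± 6595 CPM (log2 fold change -0.64, adjusted p = 0.245). Ins1 and Ins2 are paralogs, so the share of each in its counts is uncertain. In a list of genes normally silent in beta cells or raised in dedifferentiation, 10 of 20 rose and 2 fell, also adjusted over the list alone (0.00505, and adjusted p = 0.499 with an estimated correlation). The 2 that fell were Fev and Neurog3, and Aldh1a3, Gast, Sox9 and Cck were not called. Those that rose included Zyx, Ldha, Cat and Hk2. Whole islets were sequenced, so the list does not show dedifferentiation of beta cells. Slc16a1, a lactate and pyruvate transporter, rose from 0.450 ± 0.139 to 12.4 ± 2.87 CPM.

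Of 28 genes of glycolysis and hypoxia 9 rose and 4 fell, or 10 and 4 adjusted over the list alone (0.026, and adjusted p = 0.65 with an estimated correlation). Slc2a1, the ubiquitous glucose transporter GLUT1, rose from 35.7 ± 20.5 to 210.1 ± 10.53 CPM. Among 27 genes of cholesterol and fatty acid synthesis, 11 fell and 1 rose, or 11 and 2 adjusted over the list alone (0.0188, and adjusted p = 0.557 with an estimated correlation). In the lysosome, autophagy and uptake list 10 of 27 rose and 2 fell, also adjusted over the list alone (0.0433, and adjusted p = 0.419 with an estimated correlation), with Gpnmb, a lysosomal glycoprotein of phagocytes, at 273 ± 44.7 against 37.4 ± 20.4 CPM. Lists that were not called comprised extracellular matrix and wound response (11 of 25 higher and 2 lower, adjusted p = 0.059), metallothionein and metal response (5 of 11 higher and 1 lower, adjusted p = 0.059), glutamine and glutamate metabolism (3 of 22 higher and 6 lower, adjusted p = 0.713), nuclear oxidative phosphorylation (3 of 30 higher and 2 lower, adjusted p = 0.628) and proliferation (3 of 25 higher and 2 lower, adjusted p = 0.502). Adjusted over the list alone, these numbers of higher and lower members were 11 and 2, 6 and 2, 3 and 6, 3 and 1, and 3 and 1. The glycolysis call was lost without control replicate 1, control replicate 2 or inflamed replicate 3 (adjusted p up to 0.0845), the cholesterol call without control replicate 2 (0.0564), and the lysosome call without control replicate 2, inflamed replicate 2, inflamed replicate 3 or particle replicate 2 (up to 0.0873). The matrix list was called higher without control replicate 2, inflamed replicate 2 or particle replicate 2 (down to 0.00295), and the metallothionein list without control replicate 1, control replicate 3, particle replicate 2 or particle replicate 3 (down to 0.0165).

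Markers of other cell types shifted with the cytokines. Of 21 macrophage markers 19 rose and 1 fell, also adjusted over the list alone (2.01e-15, and adjusted p = 0.0293 with an estimated correlation). Cd74, the invariant chain of MHC class II, rose from 26.8 ± 11.5 to 2362 ± 55.3 CPM, and C1qc, a chain of complement C1q made by macrophages, from 27.2 to 120.5 ± 19.6 CPM. Alpha cell markers fell as a list (0.0188, and adjusted p = 0.557 with an estimated correlation), with 6 of 11 lower and 1 higher, also adjusted over the list alone. Irx2, a transcription factor of alpha cells, fell from 17.9 ± 7.27 to 2.14 ± 1.03 CPM. Gcg, which encodes glucagon (ENSMUSG00000000394, chromosome 2 from 62304874 to 62313994), went from 15880 ± 9806 to 247 ± 183 CPM (log2 fold change -6.01, SE 1.39, adjusted p = 0.0248, and -6.71 without inflamed replicate 3), a call that was lost without any 1 of the 3 control or 3 inflamed libraries (adjusted p up to 0.0818). Of 16 endothelial markers 8 fell and 0 rose, or 10 and 0 adjusted over the list alone (0.015, and adjusted p = 0.612 with an estimated correlation). Esam, a junction protein of endothelium, fell from 14.1 ± 1.67 to 3.50 ± 1.57 CPM. Not called were the lists of delta, PP and epsilon cells (1 of 10 higher and 3 lower, adjusted p = 0.287), acinar cells (0 of 23 higher and 1 lower, adjusted p = 0.534), duct (6 of 14 higher and 3 lower, adjusted p = 0.628), stellate cells (0 of 17 higher and 3 lower, adjusted p = 0.0747), lymphocytes and neutrophils (3 of 7 higher and 1 lower, adjusted p = 0.275) and neural cells (1 of 8 higher and 2 lower, adjusted p = 0.979). Adjusted over the list alone, the higher and lower members were 1 and 4, 0 and 1, 6 and 3, 0 and 0, 4 and 1, and 1 and 2. In the neural list the median and mean of the fold changes were positive and the test was negative in sign. Sst, the delta cell hormone somatostatin, was not called at 226 ± 108 against 1851 ± 799 CPM (adjusted p = 0.0864), but passed without any 1 of the 3 particle libraries (adjusted p down to 7.14e-04 over its alternatives). The delta list was called lower without particle replicate 2 (0.00871), and the stellate list without control replicate 1, control replicate 3, inflamed replicate 1 or particle replicate 2 (down to 0.0279).

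In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3568 genes were higher and 3274 lower in inflamed than in control islets, of which 2549 and 2542 changed at least 2-fold. The counts were 2278 and 2401 without control replicate 3, and no other omission moved either count by more than 1.5 times. Of the 31 lists, 12 were called higher and 7 lower with the preset correlation, and the interferon, MHC class I and macrophage calls held with an estimated one.

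**Figure D2:**
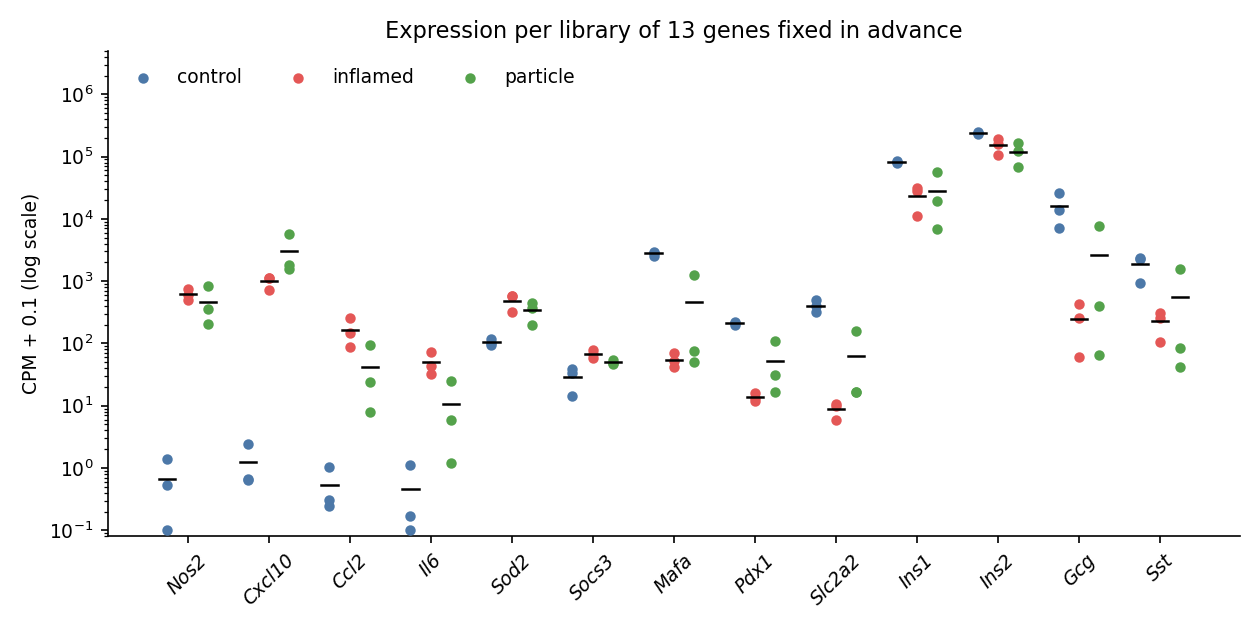
CPM of 13 genes chosen in advance (x axis) in each library, plotted as CPM + 0.1 on a log scale (y axis), with points for libraries colored by group and a bar at each group mean, n = 3. Nos2 and Cxcl10 are near the floor in control islets and high in both treated groups, while the particle libraries spread widely for Mafa, at 463 ± 693 CPM (SD), and Gcg, at 2668 ± 4226 CPM.

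To measure what the particles changed under inflammation, particle islets were compared with inflamed islets. No single gene passed the test, and macrophage genes were among those with the smallest adjusted p. C1qc (ENSMUSG00000036896, chromosome 4 from 136617115 to 136620376) was at 31.02 ± 9.6 CPM (SD, n = 3) in particle and 120.5 ± 19.6 CPM in inflamed islets, a log2 fold change of -1.96 (SE 0.25) with lower values in 3 of 3 particle libraries and an adjusted p of 0.0638. Over its alternatives that p ranged from 2.11e-08 to 0.263, and C1qc was called by DESeq2, by limma on FPKM and without particle replicate 3. C1qb, another C1q chain, was at 42.4 ± 14.1 against 147 ± 26.4 CPM (adjusted p = 0.068), and Trem2, a lipid-sensing receptor of macrophages, at 6.702 ± 1.698 against 22.5 ± 2.27 CPM (adjusted p = 0.068). Beta cell genes had higher means in particle islets with wide spread. Mafa was at 463 ± 693 against 54.4 ± 14.6 CPM (log2 fold change 3.09, adjusted p = 0.233) and Slc2a2 at 63.6 ± 81.9 against 8.67 ± 2.47 CPM (log2 fold change 2.88, adjusted p = 0.185). Particle replicate 2 held most of this, with Mafa at 1263 CPM against 74.5 and 50.7 CPM in particle replicates 1 and 3, and Slc2a2 at 158.1 against 16.3 and 16.4 CPM. Without particle replicate 2 the log2 fold changes of Mafa and Slc2a2 were 0.21 and 0.92 (adjusted p = 0.873 and 0.341), and without particle replicate 3 both passed (adjusted p = 0.0418 and 0.036).

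The macrophage list was lower in particle than in inflamed islets in every test used (camera adjusted p = 2.72e-21, adjusted p = 0.0293 with an estimated correlation, fry adjusted p = 7.33e-04). In other splits of these libraries camera at the preset correlation called 8 to 23 lists, fry up to 2, and the estimated correlation 0. The number of lists called by camera or fry thus does not set the real groups apart, and 10 splits are too few for a share under 0.05. The 21 members of the macrophage list had a median log2 fold change of -1.31, 20 were negative, 0 passed over all genes and 16 were lower adjusted over the list alone. The MHC class II members Cd74, H2-Aa, H2-Ab1 and H2-Eb1 had log2 fold changes of -0.19, -0.11, -0.46 and -0.65, and none was among the 16. Insulin took 15.4 ± 6.56% of counts in particle and 17.7 ± 4.23% in inflamed islets (exact permutation p = 0.7), and long noncoding RNAs took 0.888 ± 0.0293% and 0.698 ± 0.0619% (exact permutation p = 0.1, the smallest possible). Genes detected numbered 22715 ± 1244 and 20012 ± 2378 (exact permutation p = 0.2). Thinned to equal depth, inflamed replicates 2 and 3 held 18918 and 18102 genes and inflamed replicate 1 held 22335. The control and particle libraries held 20973 to 23438. Of 31 interferon response genes 0 passed in either adjustment, and the list was not called (adjusted p = 0.297), nor was MHC class I (adjusted p = 0.324), with 0 of 18 members called in either adjustment. Cxcl10 was at 3038 ± 2316 against 993 ± 236 CPM (adjusted p = 0.225) and Nos2 at 469 ± 337 against 618 ± 118 CPM (adjusted p = 0.828). Particle replicate 1 held most of the Cxcl10 difference, at 5709 CPM against 1829 and 1577 CPM in particle replicates 2 and 3. The inflamed libraries were at most at 1140 CPM. NF-kB targets and chemokines were lower as a list, with 0 of 30 members called over all genes and 3 lower adjusted over the list alone (1.38e-08, adjusted p = 0.383 with an estimated correlation, and fry adjusted p = 0.159). Bcl3, a nuclear NF-kB regulator, was at 59.5 ± 4.74 against 117 ± 28.6 CPM (adjusted p = 0.121), and Ccl2 at 41.7 ± 45.6 against 164 ± 88.3 CPM (adjusted p = 0.326). Extracellular matrix and wound response genes were lower as a list, with 0 of 25 called over all genes and 3 lower adjusted over the list alone (1.80e-08, adjusted p = 0.383 with an estimated correlation, and fry adjusted p = 0.167). They included Mmp14, a membrane-bound collagenase, at 20.1 ± 3.49 against 66.5 ± 14.6 CPM (adjusted p = 0.112).

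Beta cell identity was higher as a list in particle islets with camera at the preset correlation (2.62e-11). It was not called with an estimated correlation (adjusted p = 0.383) or with fry (adjusted p = 0.161). None of its 27 members passed over all genes, 21 were higher adjusted over the list alone, and 25 had a positive fold change. The list was called without any 1 library, with an adjusted p of at most 5.79e-07, but the highest levels stood in particle replicate 2. G6pc2 was at 624.2 CPM there against 53.0 and 7.93 CPM in particle replicates 1 and 3, and Pdx1 at 108.7 against 30.7 and 16.5 CPM. Without particle replicate 2 the log2 fold change of Pdx1 was 0.80 instead of 1.94, and that of Glp1r 1.07 instead of 1.83. Glp1r, the receptor of the incretin GLP-1, was at 133 ± 102 against 37.3 ± 9.86 CPM (adjusted p = 0.157) and Isl1, an islet transcription factor, at 46.7 ± 15.2 against 22.4 ± 1.76 CPM (adjusted p = 0.121). Stimulus-secretion coupling was higher as a list, with 0 of 28 members called and 10 higher adjusted over the list alone (3.17e-04, and adjusted p = 0.499 with an estimated correlation), a call that was lost without inflamed replicate 3 (adjusted p = 0.0596). Sytl4 was at 62.0 ± 35.6 against 22.5 ± 2.38 CPM (adjusted p = 0.147). Hormone processing was not called (adjusted p = 0.97, 0 of 17 members in either adjustment). Ins1 and Ins2 were not called, at log2 fold changes of 0.25 and -0.38, and Ins1 was at -0.82 without particle replicate 2 and -0.08 without inflamed replicate 2. The list of genes normally silent in beta cells or raised in dedifferentiation was lower, with 0 of 20 called and 2 lower adjusted over the list alone (7.46e-05, and adjusted p = 0.383 with an estimated correlation). Zyx, a focal adhesion protein in that list, was at 62.4 ± 14.3 against 172 ± 40.2 CPM (adjusted p = 0.0707).

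In the other lists called, no member passed over all genes. IL-6, STAT3 and acute phase genes were lower (1.04e-04, and adjusted p = 0.383 with an estimated correlation), with 3 of 27 lower adjusted over the list alone and the call made without any 1 library. Immediate early genes were lower (0.00201, and adjusted p = 0.419 with an estimated correlation; 2 of 20 lower adjusted over the list alone), a call lost without inflamed replicate 1 (adjusted p = 0.0503). Nitric oxide and NRF2 genes were lower (0.00839, and adjusted p = 0.431 with an estimated correlation; 0 of 27 adjusted over the list alone), a call lost without inflamed replicate 3 (adjusted p = 0.373). Lysosome genes were lower (0.00979, and adjusted p = 0.383 with an estimated correlation), with 3 of 27 lower adjusted over the list alone, and the call was lost without inflamed replicate 3 or particle replicate 3 (adjusted p up to 0.0788). The cholesterol synthesis list was higher (0.0432, and adjusted p = 0.612 with an estimated correlation), with 1 of 27 higher adjusted over the list alone. The apoptosis list, which mixes genes that promote and restrain cell death, was lower (0.0357, and adjusted p = 0.544 with an estimated correlation), with 0 of 27 called adjusted over the list alone. Both of these calls were lost without inflamed replicate 1, inflamed replicate 3 or particle replicate 2 (adjusted p up to 0.212 and 0.516). Neural markers were lower (0.0225, and adjusted p = 0.499 with an estimated correlation), with 1 of 8 higher and 3 lower adjusted over the list alone. Their call was lost without control replicate 2, inflamed replicate 1, inflamed replicate 3, particle replicate 1 or particle replicate 3 (up to 0.245). Sox10, a Schwann cell transcription factor, was at 1.31 ± 0.776 against 17.2 ± 16.1 CPM (adjusted p = 0.169). Lymphocyte and neutrophil markers were lower (0.0416, and adjusted p = 0.383 with an estimated correlation; 0 of 7 adjusted over the list alone), a call held only without particle replicate 3 and lost without any 1 of the other 8 libraries (up to 0.298).

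The remaining lists were not called in particle against inflamed islets, with 0 members called over all genes. These were complement (adjusted p = 0.56), metallothionein (0.0798), endoplasmic reticulum stress (0.377), the integrated stress response (0.059), glutamine metabolism (0.911), glycolysis (0.502), oxidative phosphorylation (0.677) and proliferation (0.399), and the alpha (0.377), delta (0.628), acinar (0.148), duct (0.61), stellate (0.245) and endothelial (0.459) markers. Adjusted over the list alone, 4 members were higher in the integrated stress response, among them Chac1, a glutathione-degrading enzyme, at 87.6 ± 34.8 against 39.6 ± 4.31 CPM. In the same adjustment 2 were lower in the metallothionein list, 1 in the glutamine and 1 in the endothelial list, and 1 was higher and 1 lower in each of the glycolysis, alpha and delta lists. In the glutamine, hormone processing, oxidative phosphorylation, delta and stellate lists the median, mean and test did not share 1 sign. Some lists not called with all libraries passed when 1 library was left out. Without particle replicate 2, interferon was called higher (4.83e-05) and delta lower (3.58e-04). Without particle replicate 1, MHC class I and complement were called lower (0.00248 and 0.0204), and alpha and endothelial higher (0.0417 and 0.00549). Metallothionein was called lower without particle replicate 3 (0.0193). The stress response list was called higher without control replicate 2 (0.0476), and duct lower without inflamed replicate 2 (0.026). Acinar was called higher without inflamed replicate 3 or particle replicate 1 (down to 6.87e-05). Stellate was called lower without inflamed replicate 2 or particle replicate 2 (down to 1.33e-04).

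In edgeR's quasi-likelihood test 0 genes were higher and 0 lower in particle than in inflamed islets (smallest adjusted p 0.0638), while 2603 genes had an unadjusted p under 0.05, 1655 higher and 948 lower, against 863.8 by chance. The 863.8 is a mean without a spread, and genes that shift together in 1 library move such a count. It was not counted in other splits, so the excess was not tested. DESeq2 called 527 higher and 288 lower, limma-voom 1 and 7, and limma on FPKM 0 and 10, or 5 and 6 with the smaller pseudocount and 0 and 0 without the count filter. Without particle replicate 3 the edgeR counts were 636 and 306, and without control replicate 2 they were 0 and 1. Of the 31 lists 3 were called higher and 11 lower with the preset correlation, and 1 of these, the macrophage list, held with an estimated one. Fry likewise called only the macrophage list. With the preset correlation, 5 of 10 splits of the inflamed and particle libraries, the real one among them, called at least 14 lists. That number of lists therefore does not set the real groups apart. Without inflamed replicate 3 and without inflamed replicate 1, 8 and 9 lists were called.

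**Figure D3:**
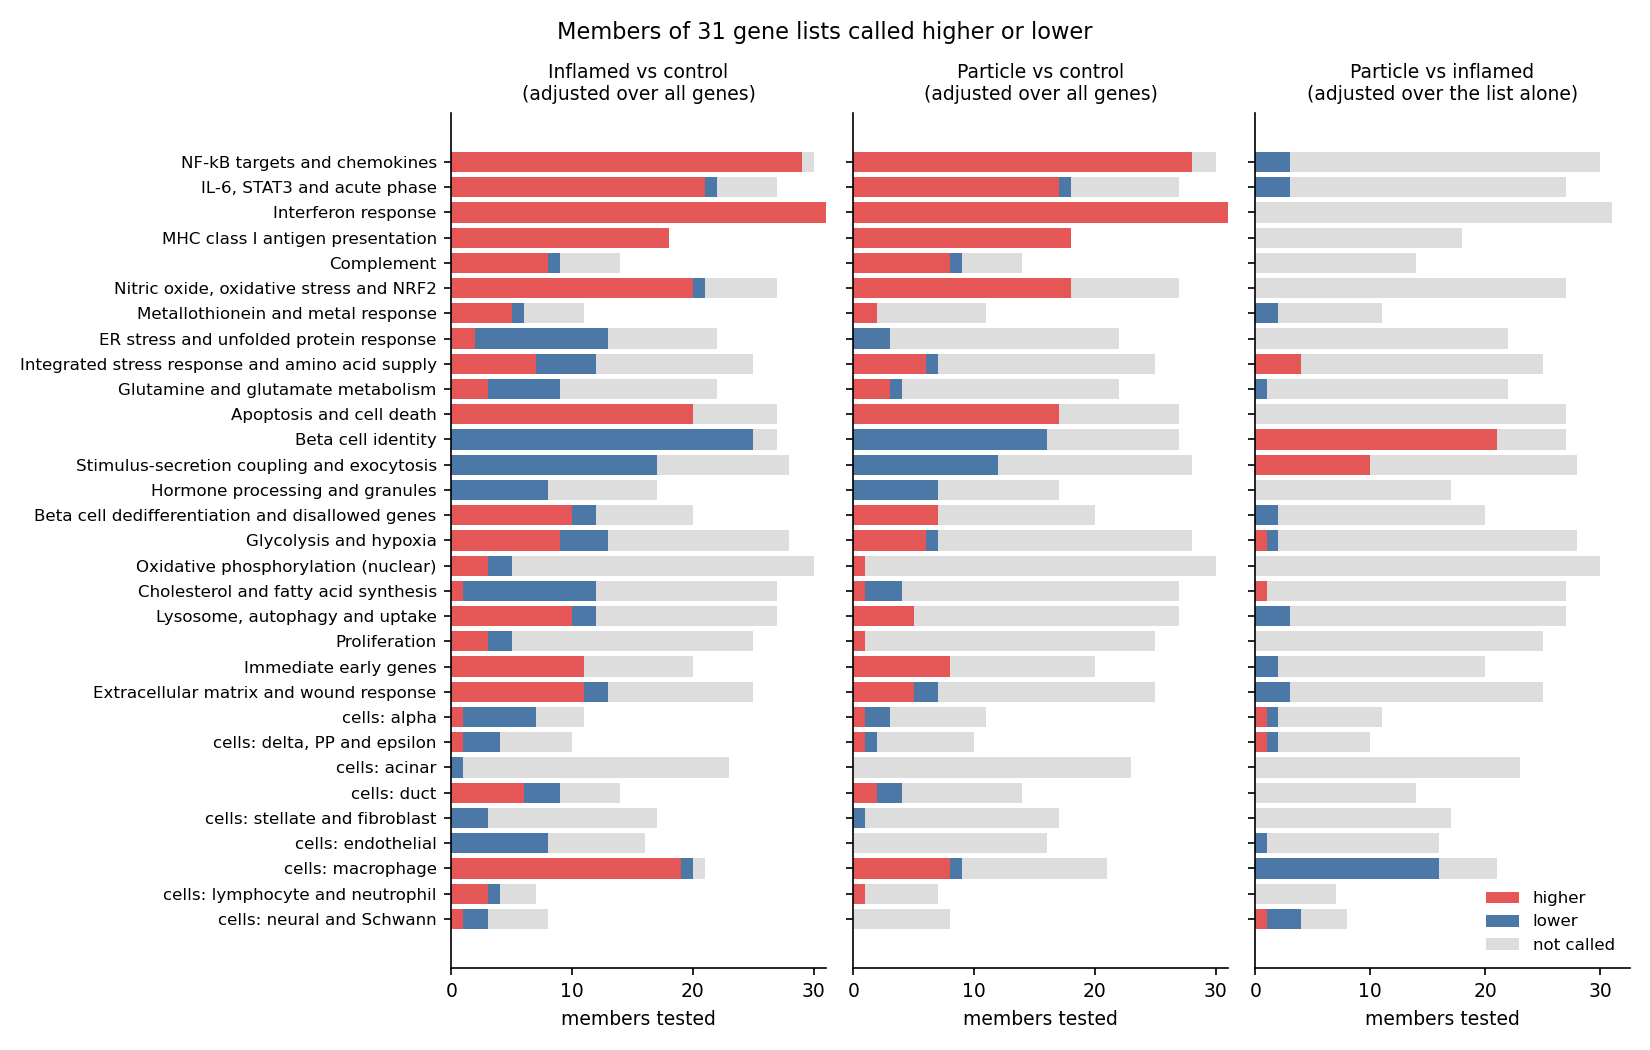
Number of tested members (x axis) of each of 31 gene lists (y axis) called higher, lower or not called, in inflamed against control and particle against control islets after adjustment over all genes, and in particle against inflamed islets after adjustment over the list alone. All 31 interferon response genes were higher in both treated groups than in control islets, and 16 of 21 macrophage markers were lower in particle than in inflamed islets.

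To ask how far particle-treated islets still differed from untreated ones, particle islets were compared with control islets. Nos2 was at 469 ± 337 CPM (SD, n = 3) against 0.573 ± 0.656 CPM (log2 fold change 9.71, SE 0.81, adjusted p = 1.42e-04), and Cxcl10 at 3038 ± 2316 against 1.14 ± 1.01 CPM (log2 fold change 11.41, SE 0.62, adjusted p = 1.13e-05). The log2 fold change of Nos2 ranged from 8.95 (without particle replicate 1) to 10.96 (without control replicate 2) and also moved over 1.5 times without control replicate 1, and that of Cxcl10 was 12.38 and 10.57 without control replicate 2 and particle replicate 1. Mlxipl, which encodes the glucose-responsive transcription factor ChREBP, fell from 681 ± 28.7 to 153 ± 80.3 CPM (log2 fold change -2.16, SE 0.37, adjusted p = 0.00431), and Slc30a8 from 441 ± 47.4 to 106 ± 72.7 CPM (log2 fold change -2.06, SE 0.38, adjusted p = 0.00608, and -2.81 without particle replicate 2).

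All 31 interferon response genes rose (6.23e-121, and adjusted p = 0.0293 with an estimated correlation), as did all 18 genes of MHC class I presentation (7.59e-70, and adjusted p = 0.0293 with an estimated correlation), both also adjusted over the list alone. Rsad2 was at 181 ± 38.6 against 1.84 ± 0.201 CPM and B2m at 4894 ± 1942 against 39.3 ± 4.02 CPM. Of 30 NF-kB targets and chemokines 28 rose and 0 fell, also adjusted over the list alone (9.93e-38, and adjusted p = 0.0958 with an estimated correlation), with Cd40 at 139 ± 61.1 against 1.203 ± 0.0501 CPM. Ccl2 rose (41.7 ± 45.6 against 0.423 ± 0.431 CPM, adjusted p = 0.00674), a call lost without control replicate 3 (adjusted p = 0.051). Il6 rose (10.53 ± 12.6 against 0.361 ± 0.565 CPM, adjusted p = 0.0444), a call lost without control replicate 1, control replicate 3, any 1 of the 3 inflamed libraries, particle replicate 1 or particle replicate 3 and with limma on FPKM (adjusted p up to 0.182). Of 27 IL-6, STAT3 and acute phase genes 17 rose and 1 fell, or 20 and 1 adjusted over the list alone (1.67e-07, and adjusted p = 0.294 with an estimated correlation). Complement genes were 8 higher and 1 lower of 14, also adjusted over the list alone (1.23e-08, and adjusted p = 0.14 with an estimated correlation). Serping1, the C1 inhibitor, was at 1027 ± 622 against 51.8 ± 15.2 CPM. Nitric oxide and NRF2 genes were 18 higher and 0 lower of 27, or 19 and 1 adjusted over the list alone (2.41e-08, and adjusted p = 0.177 with an estimated correlation). Srxn1, an NRF2-induced sulfiredoxin, rose from 98.6 ± 12.95 to 347 ± 35.2 CPM. Apoptosis genes were 17 higher and 0 lower of 27, also adjusted over the list alone (3.43e-18, and adjusted p = 0.0958 with an estimated correlation), with Fas at 49.1 ± 14.3 against 0.222 ± 0.143 CPM. Bcl2l1, Mcl1 and Cflar, which restrain cell death, were again among the higher ones. Macrophage markers were 8 higher and 1 lower of 21, or 9 and 2 adjusted over the list alone (3.08e-07, and adjusted p = 0.138 with an estimated correlation). The higher ones included the MHC class II members Cd74 (2063 ± 674 against 26.8 ± 11.5 CPM) and H2-Aa (286 ± 168 against 6.82 ± 2.80 CPM). H2-Ab1 and H2-Eb1, also of class II, and Cd68, Ctss, Fcer1g and Itgam were the others. The lower one was C1qa. C1qc (31.02 ± 9.6 against 27.2 CPM) and Trem2 (6.702 ± 1.698 against 7.11 CPM) were not called. Of all 21 markers, 18 had a positive fold change.

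Beta cell identity was lower, with 16 of 27 members lower and 0 higher, or 25 lower adjusted over the list alone (1.07e-14, and adjusted p = 0.353 with an estimated correlation). Myt1, an endocrine transcription factor, fell from 33.4 ± 3.42 to 12.8 ± 1.57 CPM. Pdx1, which overlaps Plut, fell from 212 ± 11.9 to 52.0 ± 49.7 CPM (adjusted p = 0.0303), a call lost without any 1 of the 3 control libraries, particle replicate 1 or particle replicate 3 (adjusted p up to 0.102). Mafa was not called at 463 ± 693 against 2781 ± 228 CPM (log2 fold change -2.59, adjusted p = 0.123), nor was Slc2a2 at 63.6 ± 81.9 against 402.5 ± 88.2 CPM (log2 fold change -2.66, adjusted p = 0.0579). Both passed without particle replicate 2, with log2 fold changes of -5.51 (Mafa) and -4.67 (Slc2a2), as did Ins1, Ins2, Gcg and Sst, whose adjusted p values with all libraries were 0.124, 0.117, 0.262 and 0.351 and went down to 0.00766, 0.00502, 0.00426 and 3.58e-04 over their alternatives. Stimulus-secretion coupling was 12 lower and 0 higher of 28, or 15 and 0 adjusted over the list alone (1.90e-06, and adjusted p = 0.409 with an estimated correlation). Hormone processing was 7 lower and 0 higher of 17, or 9 and 0 adjusted over the list alone (1.90e-04, and adjusted p = 0.383 with an estimated correlation), with Scg2 at 1044 ± 640 against 3708 ± 134 CPM. Endoplasmic reticulum stress genes were 3 lower and 0 higher of 22, or 1 and 0 adjusted over the list alone (0.00673, and adjusted p = 0.44 with an estimated correlation). Atp2a2 fell from 1249 ± 66.2 to 466 ± 96.1 CPM.

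Among the other lists, glycolysis and hypoxia was higher (6 of 28 higher and 1 lower, or 9 and 2 adjusted over the list alone; 0.0104, and adjusted p = 0.612 with an estimated correlation), with Slc2a1 at 203 ± 54.2 against 35.7 ± 20.5 CPM. The integrated stress response was higher (6 of 25 higher and 1 lower, or 7 and 2 adjusted over the list alone; 0.0235, and adjusted p = 0.322 with an estimated correlation). This call was lost without particle replicate 2 (adjusted p = 0.13). Atf3 rose from 5.77 ± 0.453 to 198 ± 37.8 CPM. Immediate early genes were higher (8 of 20 higher and 0 lower, or 9 and 1 adjusted over the list alone; 0.0155, and adjusted p = 0.499 with an estimated correlation). That call was lost without control replicate 1 or particle replicate 2 (adjusted p up to 0.0645). Alpha (0.00534, 2 of 11 lower and 1 higher), stellate (0.00201, 1 of 17 lower and 0 higher) and endothelial (0.00453, 0 of 16 called) markers were lower as lists, with adjusted p = 0.452, 0.499 and 0.499 with an estimated correlation and the same numbers adjusted over the list alone. Pdgfrb, a receptor of pericytes and fibroblasts, fell from 17.4 ± 3.13 to 4.23 ± 3.03 CPM. Not called were dedifferentiation (7 of 20 higher and 0 lower, adjusted p = 0.103), metallothionein (2 of 11 higher and 0 lower, 0.0798), glutamine (3 of 22 higher and 1 lower, 0.628), oxidative phosphorylation (1 of 30 higher and 0 lower, 0.677), cholesterol (1 of 27 higher and 3 lower, 0.059), lysosome (5 of 27 higher and 0 lower, 0.269), proliferation (1 of 25 higher and 0 lower, 0.677) and extracellular matrix (5 of 25 higher and 2 lower, 0.723). Adjusted over the list alone the higher and lower members were 8 and 1, 3 and 0, 4 and 1, 1 and 0, 1 and 3, 6 and 1, 1 and 0, and 6 and 2. Also not called were the delta (1 of 10 higher and 1 lower, 0.0689), acinar (0 of 23, 0.983), duct (2 of 14 higher and 2 lower, or 4 and 2 adjusted over the list alone, 0.677), lymphocyte (1 of 7 higher, 0.677) and neural (0 of 8, 0.129) markers. In the extracellular matrix and acinar lists the median, mean and test did not share 1 sign. Dedifferentiation passed without control replicate 3 or particle replicate 1 (down to 0.0357) and metallothionein without control replicate 1 or particle replicate 3 (down to 0.0262). Cholesterol passed without control replicate 1, control replicate 3 or particle replicate 2 (down to 0.00739), delta without control replicate 1, inflamed replicate 2, particle replicate 2 or particle replicate 3 (down to 1.33e-04), and neural without control replicate 1 (0.0176).

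In edgeR's quasi-likelihood test 1961 genes were higher and 1022 lower in particle than in control islets, of which 1478 and 745 changed at least 2-fold. The higher share was 65.7%, and 84.2% when library totals replaced the TMM factors, which shifted the median fold change by 0.27 on the log2 scale (0.18 for inflamed against control, where 52.1% and 61.9% were higher). Higher and lower counts were 1179 and 488 without control replicate 1, 1023 and 328 without control replicate 2, and 887 and 228 without control replicate 3. They were 1258 and 224 without particle replicate 1, 2424 and 2121 without particle replicate 2, and 1158 and 307 without particle replicate 3. Of the 31 lists 11 were called higher and 7 lower with the preset correlation, and the interferon and MHC class I calls held with an estimated one.

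To count genes that the cytokines changed and the particles returned toward control, calls of the first and second comparisons were combined. Of the 3568 genes raised by cytokines 0 were lower in particle than in inflamed islets, and of the 3274 lowered genes 0 were higher, where 0 and 0 were expected from independent lists. With 0 genes called in particle against inflamed islets, these counts and expected values are fixed at 0 and do not test a return toward control. DESeq2 gave 250 and 503 such genes (35.9 and 71.7 expected), the edgeR fit without the count filter 86 and 117 (10.5 and 13.3 expected), and the fit without particle replicate 3 294 and 624 (64.8 and 125 expected). Limma-voom gave 7 and 1, library totals 0 and 1, and the fit without control replicate 2 1 and 0. Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a correlation of -0.69 and a covariance of -1.30, and 77.7% were opposite in sign. Both comparisons use the inflamed libraries, which alone gives opposite signs. In 20 simulations with no effect the correlation was -0.493, the covariance -0.169 (-0.189 to -0.159) and the opposite share 66.6%, and in 20 simulations with the cytokine effect alone they were -0.142, -0.165 (-0.191 to -0.146) and 55.4%. Without particle replicate 2 the observed values were -0.427, -0.857 and 66.7%, and without inflamed replicate 1 they were -0.756, -2.39 and 78.8%. With all libraries the observed covariance lay outside the range of both sets of simulations. Each gene was drawn independently there, so shifts of a whole library, such as that of particle replicate 2, were absent. Those ranges therefore cannot tell a particle effect from shifts of single libraries. The 3 inflamed libraries cannot be split into parts of at least 2 for a direct test.

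**Figure D4:**
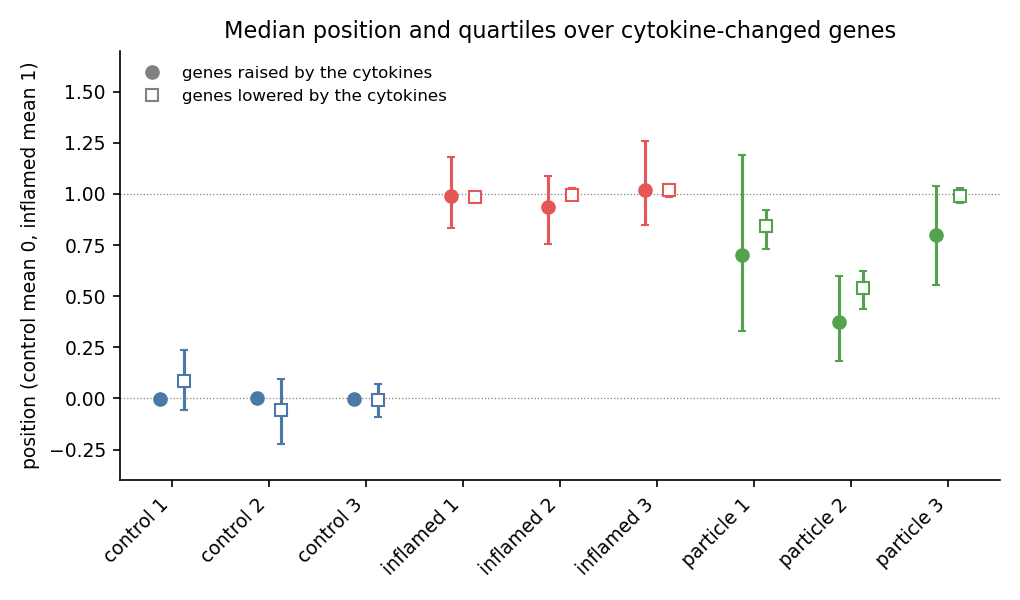
Median position of each library (x axis) between the control mean (0) and the inflamed mean (1) on the y axis, over 639 genes raised (filled circles) and 579 genes lowered (open squares) at least 4-fold by the cytokines, a choice made after the data were examined. Bars span the quartiles over genes. Particle replicate 2 lies at 0.375 and 0.541, below particle replicates 1 (0.700 and 0.841) and 3 (0.797 and 0.992).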

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

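Thinning to equal depth was chosen after seeing the data. No call with all libraries turned its direction under any alternative run. Inflamed against control gave 3568 genes higher and 3274 lower. These counts were 2146 and 2020 with glmTreat, which tests against a larger fold, and 2278 to 3786 and 2401 to 3588 with 1 library left out. Particle against inflamed gave 0 and 0. The counts were 1 and 0 with library totals, 120 and 101 without the count filter, 527 and 288 with DESeq2, 1 and 7 with limma-voom, 0 and 10 with log2(FPKM + 1) and 5 and 6 with log2(FPKM + 0.1). With 1 library left out they were 0 to 636 and 0 to 306. Particle against control gave 1961 and 1022. The counts were 3193 and 597 with library totals, 2303 and 1894 with DESeq2, 948 and 127 with glmTreat, 1504 and 2022 with log2(FPKM + 1), 1653 and 1622 with log2(FPKM + 0.1), and 969 and 1048 with FPKM and no count filter. With 1 library left out they were 887 to 2424 and 224 to 2121. Leave-one-out fits have fewer samples, and the cause of the other differences was not tested.

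Genes raised or lowered by the cytokines and moved back with particles numbered 0 and 0. They numbered 0 and 1 with library totals, 86 and 117 without the count filter, 250 and 503 with DESeq2, 7 and 1 with limma-voom, and 0 to 294 and 0 to 624 with 1 library left out. Lists called with the preset correlation numbered 19, 14 and 18 in inflamed against control, particle against inflamed and particle against control. With an estimated correlation they numbered 3, 1 and 2, and with fry 19, 1 and 16. With 1 library left out, particle against inflamed gave 8 to 17 lists. The replicate numbers did not pair the libraries. Deviations from the group means of libraries with the same number had correlations of -0.184 to 0.206, and 1 of 9 libraries correlated best with its own number. With the replicate number as a block the genes called higher and lower were 3152 and 2964, 0 and 0, and 1628 and 970 in the same order. With it, the calls of Ins1 and Gcg in inflamed against control and of Il6 in particle against control were not made. Thinning every library to the smallest total gave 3525 and 3238, 0 and 0, and 1962 and 1088, so depth moved these counts little.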

Other observations

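The tests of a mislabelled sample, of mixed RNA, of fewer macrophages and of every interferon source, the count of acinar markers in particle replicate 2, the split counts with an estimated correlation or fry, and the genes named in the next paragraph were chosen after the results were seen.

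In particle against inflamed islets 22 genes had an adjusted p under 0.1, of which 18 were lower and 4 higher, and in all 22 the particle and inflamed libraries did not overlap. None passed the test. Of the 18 lower ones 17 had been raised by the cytokines, and the 4 higher ones had been lowered by them. Both comparisons share the inflamed libraries, which favors such opposite signs. Laptm5, a lysosomal protein of blood cells, was at 18.7 ± 6.52 CPM (SD, n = 3) in control, 54.3 ± 5.47 in inflamed and 15.3 ± 2.57 in particle islets (adjusted p = 0.0638). Cyba, a subunit of the phagocyte NADPH oxidase, was at 7.25 ± 1.63, 108.5 ± 25.8 and 33.03 ± 10.65 CPM (adjusted p = 0.0697). Sh3pxd2b, a scaffold of podosomes, was at 4.61 ± 1.10, 28 ± 6.40 and 6.32 ± 1.37 CPM (adjusted p = 0.0638), and Itga5, the fibronectin receptor subunit, at 7.69 ± 2.001, 24.6 ± 7.42 and 6.81 ± 1.11 CPM (adjusted p = 0.068). Ass1, the arginine-recycling enzyme argininosuccinate synthase, was at 9.02 ± 3.59, 63.9 ± 1.81 and 19.1 ± 2.47 CPM (adjusted p = 0.0697). Among the higher ones P2ry1, a purinergic receptor, was at 15.7 ± 2.63, 4.04 ± 0.494 and 12.2 ± 2.515 CPM (adjusted p = 0.068), and Nrep, a regulator of neuronal regeneration, at 29.7 ± 2.82, 4.73 ± 0.189 and 17.2 ± 4.04 CPM (adjusted p = 0.0638).

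Over genes changed by the cytokines, particle replicate 2 lay between the control and inflamed libraries, while 21 of 23 acinar markers there lay above all controls (Cel at 139.6 CPM against at most 69.7 CPM), 1 lay within them and 1, Bhlha15, below them. A mislabelled untreated sample would lie near 0 over the 639 raised genes, and its median position was 0.375. Library depth or scaling is argued against by the smallest gap to another particle library, which was 0.32 over 4 settings. RNA of untreated islets mixed into a treated library needs similar shares from raised and lowered genes, and these were 0.545 (quartiles 0.362 to 0.672) and 0.412 (0.306 to 0.511), a difference of 0.133. A weaker response of that library to cytokines predicts the same, and the bound on the difference was set after the values were seen, so a mixture and a weaker response cannot be told apart.

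Macrophage markers were lower with particles than with cytokines alone. Neither particle replicate 2 alone nor inflamed replicate 3 alone accounts for it, since the median log2 fold change was -1.22 without the first and -1.10 without the second. Fewer macrophages in the particle libraries would lower the markers alike, and 2 of 17 members outside MHC class II lay over 2 SE from their median of -1.44 (C1qc, and Cx3cr1, which was higher at 1.85), while the 4 class II members had a median of -0.33. Of the 21 markers 20 were at 1 CPM or more in control islets, and 0 belong to another list. The bound for that test was set after the values were seen, so fewer macrophages and a lower expression per macrophage both stay open.

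Interferon response genes rose although the named cytokines hold no interferon. Interferon-gamma transcribed in the islets at harvest is argued against by Ifng, whose highest count in the 6 cytokine-treated libraries was 0 (upper limit 0.0187 CPM for all 6 pooled), and Ifnb1 had 8 counts in particle replicate 1 and 0 in the other libraries. Of interferon-lambda transcribed in the islets, the 2 genes Ifnl2 and Ifnl3 were called higher, at 20.84 ± 10.15 against 0 CPM (adjusted p = 4.44e-04) and 32.18 ± 18 against 0.0582 ± 0.0506 CPM (adjusted p = 7.40e-05), though these paralogs are uncertain and Ifnl2 overlaps Samd4b. Their rise was seen before the test was chosen, so this source stays open. Ifnlr1, a subunit of their receptor, was present at 1.54, 3.44 and 2.56 CPM in control, inflamed and particle islets. Its change in inflamed against control islets was not called (adjusted p = 0.0978), and a change of the receptor was not part of the test. An interferon in the cocktail that the labels do not name cannot be told apart from one made by the islets, since RNA does not hold an added protein, and Ciita, the class II transactivator, rose by a log2 fold change of 4.94 (adjusted p = 1.66e-04).

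Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. For inflamed against control, 1 of 10 splits called as many genes (6842, highest other 0) and 3 of 10 as many lists (19, highest other 21). For particle against inflamed, 10 of 10 called as many genes in edgeR, as a count of 0 must (0, highest other 0, with 2603 at an unadjusted p under 0.05 and 527 higher and 288 lower in DESeq2), 5 of 10 as many lists (14, highest other 23), and 10 of 10 moved as many genes back, which a count of 0 also fixes (0, highest other 0). For particle against control, 1 of 10 called as many genes (2983, highest other 0) and 3 of 10 as many lists (18, highest other 20). Other splits called 10 to 21, 8 to 23 and 13 to 20 lists in that order with the preset correlation. These splits mix the groups in unequal numbers and keep part of any group difference, so their list counts cannot show that the real calls arise without one. With an estimated correlation the real splits called 3, 1 and 2 lists and the highest other splits 1, 0 and 0, and with fry the real ones called 19, 1 and 16 and the highest others 1, 2 and 0.

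Xist, the transcript of the inactive X chromosome, was at 17.39 CPM in control replicate 2 and at most 1.74 CPM in the other 8 libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together were at 71.71 CPM in control replicate 2. In the other 8 libraries they were at 67.27 to 116.6 CPM. These values are CPM of the library total.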
